A study of Homo sapiens with 4 samples.

How the data were processed

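Total RNA from 4 human prostate cancer cell cultures was measured on Affymetrix whole-transcript arrays, 1 array per culture. Per the labels' protocols, RNA was extracted with ISOGEN II and biotin-labelled with the WT Terminal Labeling Kit. The deposited values are intensity values on a linear scale, as the values themselves show, with a lowest value of 17.6 and a highest of 11188. The 4 arrays had nearly the same distribution, with medians of 41.2 (PC3-H), 39.8 (PC3-L), 40.8 (LNCaP) and 40.9 (LNCaP-AI), and values were not centred per gene. How the authors summarised probes, corrected background, normalised the arrays and filtered probes is not given in the sources used here. Every probe of the table reached at least 21.9 on 1 array. That level limits the highest value of a probe, while single values went down to 17.6. No value lay below this floor, so the fold of a gene that is dim on 1 array is understated. The series' design text names GeneSpring GX 12.6, the pairs PC3-H against PC3-L and LNCaP against LNCaP-AI, and thresholds of a false discovery rate of 10% and a 2-fold difference; with 1 array per group the first of these was not applied here.

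Groups were taken from the sample titles, and the glycan label (high or low) from the source names. The labels disagree among themselves. The free-text descriptions call PC3-H low and PC3-L high for the glycan, opposite to titles and source names, and call the LNCaP culture androgen-independent where its characteristics call it androgen-dependent. The titles and source names were followed, and the opposite assignment of the PC3 pair was run as an alternative.

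The table held 37934 probes, of which 14952 (39.4%) had 1 gene symbol, 0 had several and 22982 had none in the platform annotation used here. All 14952 matched the human RefSeq gene table (assembly GRCh38.p14) by Entrez identifier and 0 symbols needed updating. They covered 14006 genes, 583 of them with over 1 probe, and the probe with the highest mean over the 4 arrays stood for its gene. Among these 583 genes, probes went past 2-fold in opposite directions for 1 gene in the PC3 pair and 0 in the LNCaP pair; of 64 and 65 genes with any probe past 2-fold, all probes were past it in the same direction for only 15 and 13. Unnamed probes entered the distributions and correlations of the arrays, the percentiles of the filter, the normalizations and 1 alternative of the counts. CAV1, DAG1 and B4GAT1 were among the genes without a named probe and are not analysed here. Genomic sequence was not used here, and the gene table served only for names, gene lengths and the order of neighbouring genes.

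Intensities were used as deposited and taken to log2 after adding a pseudocount of 1, since they proved linear. In each pair the log2 difference was computed per gene, over genes whose higher value reached the 40th percentile of its array over all probes, and genes past 2-fold were counted. Differences carry no error, because each group had 1 array, and no p-value was given for a pair. Array number limits the precision. Gene lists were fixed before the data were examined, and counts over a list cover only its members with a named probe past the filter. For a list with at least 5 genes past the filter, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression; a percentile under 2.5 or over 97.5 was taken as standing apart. These percentiles describe the 2 arrays compared and are no test across cultures.

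The genes named were chosen by a rule fixed before the data were examined. It took the 8 largest differences in each direction per pair, without small RNAs, uncharacterised reading frames and Y-linked genes. It also took every gene of the laminin-binding glycan list, and up to 3 members past 2-fold from each other list. Across both pairs it took the 6 genes higher and the 6 genes lower in both. Line markers and the 2 most abundant members of each cell type list were added. The histone list matched 1 gene, an antisense RNA that is no histone, so it measured no histone. The small RNA list was matched by symbol prefix and also held host genes such as MIR99AHG.

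Low against high glycan label over both lines was tested with limma, with the line as a covariate and 1 residual degree of freedom, two-sided with Benjamini-Hochberg adjustment at 0.05. LNCaP against PC3 was read from the same fit. Whether differences cluster along chromosomes was examined over 11141 autosomal genes in windows of 25 neighbouring genes, with 10 and 50 as other sizes, after limiting log2 differences to 1 in either direction and against 200 shuffled gene orders. A trend with gene length and with the span of the 10 neighbouring genes was fitted as a quadratic surface and removed in 1 alternative. For the counts of a pair this removal also set the mean log2 difference to the pair's former median. Of the genes, 100% had a length and 98.3% a span; the median stood in for the others. Gene GC content was not analysed here.

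The other alternatives were quantile normalization, median centring and cyclic loess, no filter or filters at the 20th and 60th percentile, thresholds of 1.5-fold and 3-fold, the mean over probes, small RNA genes left out, random lists not matched on expression, limma with an intensity trend or a robust prior or no covariate, and the turned PC3 pair. After the data were seen, pseudocounts of 0 and 16, all probes, the removal of the length and density trend, and settings that doubt the array labelled LNCaP-AI were added.

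The limma fit, the pair calls, the list percentiles and the window tests were tested on simulated data; the overlap, the mixture share, the trend removal and the ratio of higher to lower genes were not. With 200 of 11509 genes changed by 1.5 or 3 on the log2 scale and a noise SD of 0.219, limma recovered 100% of them in the low against high comparison, with 8.3 and 8.8 false calls on average. In simulated pairs 94.9% and 100% of changed genes went past 2-fold, and 0.115% and 0.141% of unchanged ones did. Every simulated gene had the same noise SD and changed alike in both lines. In the data the standard errors of the low against high fit differed between genes, such as 0.24 for PTGFRN and 1.38 for THBS1. These simulated rates are therefore not the power or error rate of the real comparisons. Of 500 simulated lists of 15 genes among 11135 in the PC3 pair, 5.60% fell outside the percentile limits with no shift and 100% with a shift of 1. The clustering ratio over 11141 genes lay between 0.888 and 1.07 in unclustered data and between 3.73 and 4.42 with shifted windows. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.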

Results

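Gene expression was measured in 4 cultures of 2 human prostate cancer lines, with 1 array each and 14006 named genes. PC3 is an androgen-independent line from a bone metastasis, and LNCaP is an androgen-dependent line from a lymph node metastasis. PC3-H and PC3-L are PC3 cells separated with the antibody IIH6C4, which recognises the laminin-binding glycan of alpha-dystroglycan, into cells high and low for that glycan. LNCaP-AI is labelled as LNCaP made androgen-independent in medium with charcoal-stripped serum, which is depleted of steroids; its description also mentions medium conditioned by perineural cells. LNCaP is labelled high and LNCaP-AI low for the glycan. The labels give low motility and invasion to PC3-H and LNCaP and high motility and invasion to PC3-L and LNCaP-AI. No group had a replicate, so differences between arrays have no replicate check.

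The line markers were read before any comparison. KLK3, which encodes prostate-specific antigen, had an intensity of 1781 on the LNCaP array, against 59.0 on PC3-H and 63.4 on PC3-L. On the array labelled LNCaP-AI it was 61.2. FOLH1, which encodes prostate-specific membrane antigen, was 944 on LNCaP and 23.4, 23 and 24.2 on PC3-H, PC3-L and LNCaP-AI. The hyaluronan receptor CD44 was 23.9 on LNCaP and 239, 318 and 297 on the same 3 arrays, and the receptor kinase AXL was 47.4 on LNCaP and 609, 900 and 1015 on them. VIM, the intermediate filament vimentin, was 65.1 on LNCaP, 104 on PC3-H, 896 on PC3-L and 1216 on LNCaP-AI. Of 23 genes at least 8-fold higher on LNCaP than on both PC3 arrays, 23 were within 2-fold of PC3-L on the array labelled LNCaP-AI and 0 were within 2-fold of LNCaP. Of 19 genes at least 8-fold lower on LNCaP than on both PC3 arrays, 13 were within 2-fold of PC3-L there and 0 within 2-fold of LNCaP. Not every PC3 marker was at its PC3 level on the array labelled LNCaP-AI. CXCL8 was 46.9 on it, against 22.3 on LNCaP, 302 on PC3-H and 497 on PC3-L. LCN2 differed between the PC3 arrays themselves, at 1881 on PC3-H and 46.1 on PC3-L, with 64.5 on LNCaP and 46.0 on the array labelled LNCaP-AI. PC3 markers were 2-fold or more below PC3-L there in 2 of 9 and above it in 0. The array thus goes against its line label at most of these genes, and is called the array labelled LNCaP-AI throughout.

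**Figure D1:**
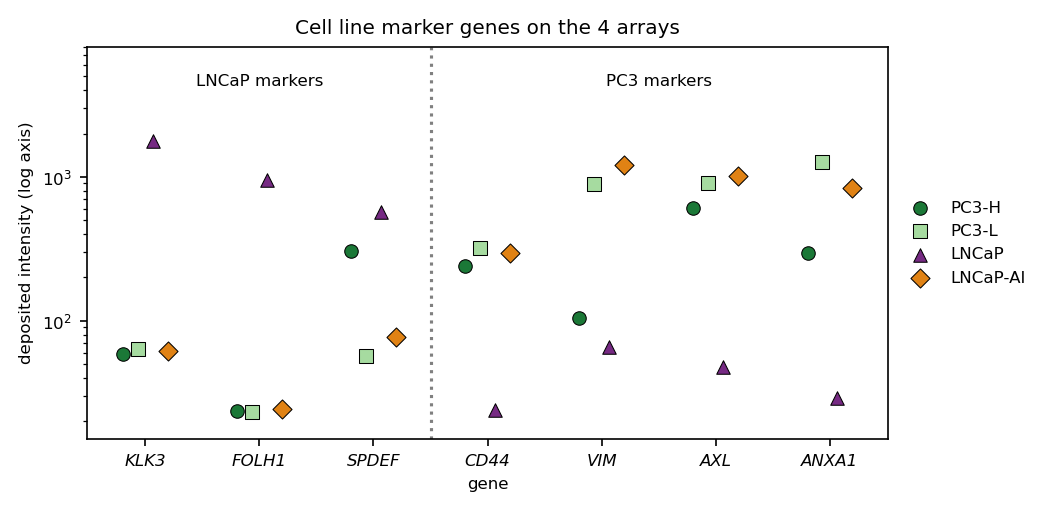
Deposited intensity (log axis) of 3 LNCaP and 4 PC3 marker genes on the 4 arrays, 1 point per array. KLK3 stands at 1781 on LNCaP and between 59.0 and 63.4 on the other 3 arrays, including the array labelled LNCaP-AI. SPDEF, listed as an LNCaP marker, did not separate the lines, at 566 on LNCaP, 306 on PC3-H, 56.5 on PC3-L and 76.6 on the array labelled LNCaP-AI. VIM, listed as a PC3 marker, was within 2-fold between LNCaP (65.1) and PC3-H (104), against 896 on PC3-L and 1216 on the array labelled LNCaP-AI.

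Across all probes on the log2 scale, the array labelled LNCaP-AI correlated most with PC3-L (r = 0.961), then with PC3-H (r = 0.926) and least with LNCaP (r = 0.885). These are correlations across probes, which are not independent replicates. PC3-H correlated with PC3-L at r = 0.899 and with LNCaP at r = 0.900, and PC3-L correlated with LNCaP at r = 0.877. Among genes past the filter, 305 (2.78%) differed by 2-fold or more between PC3-L and the array labelled LNCaP-AI, against 1373 between PC3-L and PC3-H and 1178 between LNCaP-AI and LNCaP. PC3-H differed from LNCaP at 1109 genes (9.94%) and from the array labelled LNCaP-AI at 815 (7.32%), and PC3-L differed from LNCaP at 1305 (11.7%). By these counts PC3-L was no closer to PC3-H (12.3%) than to LNCaP. In the brightest 20% of genes, 2802 in number, the array labelled LNCaP-AI correlated at r = 0.841 with PC3-L and r = 0.486 with LNCaP.

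The comparison of PC3-L with PC3-H asks what accompanies the loss of the laminin-binding glycan between the cultures labelled PC3. MMP1, an interstitial collagenase, was 111-fold higher on the PC3-L array, with an intensity of 3143 against 27.4. The membrane peptidase MME was 29.7-fold higher, the signalling ligand BMP2 14.3-fold and the matricellular gene CCN2 11-fold, and the protease inhibitor TFPI2 was 10.6-fold higher. NRIP3 (20.1-fold), AJAP1 (13.2-fold) and INSIG1 (12.2-fold) completed the 8 largest. Lower on PC3-L were the neutrophil chemokine CXCL5 (77.5-fold), the protease inhibitor SLPI (46.3-fold), the proteoglycan SRGN (42.2-fold) and the Wnt antagonist DKK1 (40.7-fold). The siderophore-binding gene LCN2 was 46.1 on PC3-L against 1881 on PC3-H. Also lower were the epithelial adhesion molecule EPCAM (21.5-fold), complement C3 (19.7-fold) and the arginine synthesis enzyme ASS1 (17.2-fold).

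Epithelial genes were lower on PC3-L as a group: 12 of 23 were past 2-fold lower and 0 higher, with a median log2 difference of −1.60 (percentile 0 of the random lists). EPCAM, the membrane protease ST14 (9.66-fold) and the keratin KRT19 (9.31-fold) had the largest differences. Of 13 mesenchymal genes 4 were higher and 1 lower (median 0.54, percentile 99.1), among them CCN2, VIM (8.55-fold) and the repressor SNAI2 (6.72-fold); the 1 lower was THBS1. Matrix-degrading proteases and their inhibitors were past 2-fold higher in 7 of 14 and lower in 1 (median 1.00, percentile 99.9), with MMP1, MMP16 (4.61-fold) and CTSB (3.75-fold). Interstitial matrix genes were higher in 4 of 9 and lower in 0 (median 0.91, percentile 99.4), namely SPP1 (7.81-fold), VCAN (5.11-fold), TNC (4.56-fold) and the cross-linking enzyme LOX (3.38-fold).

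Cholesterol synthesis and uptake genes were higher on PC3-L in 9 of 16 and lower in 1 (median 1.33, percentile 100). INSIG1, MSMO1 (8.04-fold) and STARD4 (7.27-fold) led them. Unfolded protein and amino acid stress genes were higher in 6 of 15 and lower in 1 (median 0.74, percentile 99.6), led by the serine synthesis enzyme PSAT1 (4.52-fold), the asparagine synthetase gene ASNS (4.48-fold) and VLDLR (4.20-fold). Interferon response genes were lower in 4 of 23 and higher in 2 (median −0.49, percentile 0); IFITM2 was 8.17-fold lower and ISG15 2.40-fold lower, while SAMD9 was 3.20-fold higher. Inflammatory cytokines were lower in 5 of 18 and higher in 0 (median −0.27, percentile 1.34), with CXCL5, IL18 (8.59-fold) and ICAM1 (7.21-fold); the percentile was 16.4 once a trend with gene length and density was removed. No integrin of the list of integrins and laminin receptors was measured; its 5 measured members were BCAM, CD151, CD44, SDC1 and SDC4. Of these SDC4 was past 2-fold, 2.35-fold lower, and their median was −0.73 (percentile 0.91).

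Of 19 genes listed for synthesis of the laminin-binding glycan 9 had a named probe, and these 9 did not stand apart as a group. Of them 1 was past 2-fold, LARGE2, a glycosyltransferase that extends the laminin-binding polymer, with an intensity of 54.3 on PC3-L against 160 on PC3-H (2.92-fold lower). The list median was −0.12 (percentile 21.3). The glycan kinase gene POMK had a log2 difference of 0.77, and DPM3 −0.29, POMT1 −0.20, GMPPB −0.15, POMGNT2 −0.12, POMT2 −0.04, DOLK 0.03 and RXYLT1 0.02.

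Other lists did not stand apart in the PC3 pair. Cell cycle genes were higher in 6 of 33 and lower in 1 (median 0.10, percentile 37.5), with KIF11 (2.97-fold), BUB1 (2.40-fold) and MKI67 (2.37-fold) higher; MKI67 was just within 2-fold (log2 difference 0.9993) with the length and density trend removed. Mucin-type glycan enzymes were higher in 2 of 11 and lower in 2 (percentile 51.4): GALNT14 was 4.30-fold and GALNT1 2.86-fold higher, and GALNT3 was 4.58-fold lower. Androgen-induced genes were lower in 2 of 9 (percentile 62.7), namely STEAP4 (3.06-fold) and NDRG1 (2.29-fold). Neuroendocrine genes were higher in 1 of 9, UCHL1 (3.59-fold), and lower in 1, L1CAM (2.87-fold), at percentile 33.1. Hypoxia genes were higher in 1 of 14, LOX, and lower in 1, NDRG1 (percentile 5.45), and progenitor genes were lower in 1 of 10, NES, at 42.4 against 107 (percentile 26.5). Steroid metabolism genes were past 2-fold in 0 of 5 (percentile 19.0) and ribosomal protein genes in 0 of 23 (percentile 17.3). Small RNA genes were higher in 10 of 435 and lower in 7 (percentile 57.4). Lists with under 5 measured genes were given no percentile: basement membrane genes had 1 of 4 lower, HSPG2 (2.04-fold, within 2-fold after median centring with a log2 difference of −0.98), and antigen presentation genes 0 of 2 past 2-fold. PC3 markers were higher in 3 of 9 and lower in 2 (percentile 92.0), and LNCaP markers higher in 1 of 5 and lower in 2 (percentile 34.6).

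Markers of other cell types were mostly dim in the PC3 pair, with CD68 as the brightest. The fibroblast marker THY1 was 51.5 and 51.7 on PC3-H and PC3-L and LUM had a log2 difference of −0.28, and 0 of 1 fibroblast gene passing the filter was past 2-fold. Endothelial genes were past 2-fold in 0 of 6 (percentile 23.4), with CLDN5 at 73.4 and 58.2 and ESAM at 55.7 and 40.8. Perineurial and Schwann cell genes were lower in 1 of 5 (percentile 49.1); this was ERBB3, which epithelial cells also express, at 80.8 and 38.1, and SOX10 was 60.4 and 58.3. Leukocyte genes were higher in 1 of 4, the lysosomal gene CD68, at 290 and 630, with NKG7 at 88.0 and 75.8. The erythroid gene AHSP did not pass the filter.

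In all, 955 of 11135 genes were past 2-fold higher on the PC3-L array and 418 lower, and 102 and 96 were past 4-fold. With the trend with gene length and density removed the counts were 552 and 536, so the excess of higher genes was not kept. That removal also shifted all differences of the pair by a constant, and the effect of this shift was not separated. No p-value was given, since each group had 1 array.

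The comparison of the array labelled LNCaP-AI with LNCaP asks what accompanies androgen independence and loss of the glycan. Its directions rest on an array that goes against its line label, and each gene group below was read beside the line markers. LNCaP markers were lower in 6 of 6 (median −3.10, percentile 0) and PC3 markers higher in 6 of 9 and lower in 0 (median 1.75, percentile 100). Among these, the PC3 marker CXCL8 counted as higher at 46.9 though it was 302 and 497 on the PC3 arrays. VIM and UCHL1 counted as higher too, though PC3-H was within 2-fold of LNCaP for both (104 against 65.1, and 57.4 against 54.1). The other PC3 markers counted as higher, AXL, CD44 and ANXA1, were past 2-fold higher on PC3-H than on LNCaP. The LNCaP marker SPDEF was also high on PC3-H (306, against 566 on LNCaP). The membrane gene EMP3 was 64.8-fold higher on the array labelled LNCaP-AI, MMP1 57.0-fold, TFPI2 45.0-fold and the proteoglycan VCAN 37.9-fold. The transcription factor gene FOSL1 was 33.4-fold higher, ANXA1 27.9-fold and the peptidase ANPEP 24.3-fold. ANXA2P2, a pseudogene nearly identical to ANXA2, was 37.5-fold higher, and the probe may not separate the copies. Lower on that array were GDF15 (44.0-fold), FOLH1 (37.4-fold), NETO1 (35.3-fold), SYT4 (29.2-fold), KLK3 (28.6-fold), ADGRG6 (27.0-fold), the epithelial factor EHF (24.1-fold) and the monoamine oxidase gene MAOA (23.7-fold).

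Androgen-induced genes were lower on the array labelled LNCaP-AI in 7 of 9 and higher in 0 (median −1.91, percentile 0), led by KLK3, PLPP1 (11.9-fold) and KLK4 (8.97-fold). All 3 were within 2-fold of both PC3 arrays there; PLPP1 was 136 against 139 on PC3-L. Epithelial genes were lower in 11 of 21 and higher in 0 (median −1.22, percentile 0), with the desmosomal gene DSP (583 on LNCaP against 33.3), the tight junction gene CLDN7 (11.4-fold) and EPCAM (9.18-fold). Mesenchymal genes were higher in 6 of 13 and lower in 0 (median 0.95, percentile 100), with AXL (21.0-fold), VIM (18.4-fold) and THBS1 (12.0-fold). Interstitial matrix genes were higher in 7 of 9 and lower in 0 (median 1.61, percentile 100), with VCAN, TNC (18.7-fold) and FBN2 (13.9-fold). Proteases and inhibitors were higher in 6 of 14 and lower in 1 (median 0.63, percentile 99.95), with MMP1, the membrane protease MMP14 (21.1-fold) and TIMP1 (17.9-fold). Of the 6 measured members of the laminin receptor list, again with no integrin, CD44 (12.0-fold), SDC4 (2.89-fold) and CD151 (2.61-fold) were higher and 0 lower (median 1.01, percentile 99.95); the others were BCAM, SDC1 and SDC2.

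Stress genes were lower on that array in 8 of 15 and higher in 0 (median −1.01, percentile 0), led by PSAT1 (3.32-fold), DDIT4 (3.23-fold) and PHGDH (2.95-fold). Cell cycle genes were higher in 4 of 33 and lower in 0 (median 0.38, percentile 99.9), with TOP2A (2.54-fold), CDC20 (2.26-fold) and KIF11 (2.22-fold). Interferon response genes were higher in 5 of 22 and lower in 1 (median 0.30, percentile 99.9); SAMD9 was 5.24-fold and IFI44 3.14-fold higher, and IFITM2 2.81-fold lower. The 2 antigen presentation genes measured, TAPBP (2.26-fold) and B2M (2.17-fold), were both higher; the mean over B2M's probes gave a log2 difference of 0.95. Of the 9 glycan synthesis genes 1 was past 2-fold, POMK, 2.77-fold lower with an intensity of 190 against 530 on LNCaP; LARGE2 had a log2 difference of −0.57 and the list median was −0.09 (percentile 32.7). The other 7 lay between −0.14 (POMT1) and 0.18 (POMGNT2).

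The remaining lists did not stand apart in this pair. Cholesterol genes were past 2-fold in 0 of 16 (percentile 47.5). Inflammatory genes were higher in 2 of 16 and lower in 1 (percentile 58.4), with CXCL6 5.31-fold and CXCL8 2.05-fold higher and CXCL16 2.68-fold lower. Hypoxia genes were lower in 3 of 14, including BNIP3 (3.27-fold) and BNIP3L (2.58-fold), and higher in 1, LOX (percentile 11.9). Progenitor genes were higher in 3 of 10, CD44, SOX9 (6.60-fold) and HMGA2 (3.15-fold), and lower in 1 (percentile 85.3). Mucin-type glycan enzymes were higher in 2 of 11, GALNT6 (2.55-fold) and GALNT14 (2.36-fold), and lower in 1, GALNT3 (3.01-fold; percentile 89.3). Neuroendocrine genes were lower in 2 of 10, SYT4 and CPE (2.33-fold), and higher in 1, UCHL1 (3.36-fold; percentile 29.6). Steroid metabolism genes were lower in 1 of 5, HSD17B4 (2.08-fold; percentile 14.1), ribosomal protein genes in 1 of 23, RPS24 (2.07-fold; percentile 10.9), and small RNA genes were higher in 9 of 429 and lower in 9 (percentile 92.5). Basement membrane genes were past 2-fold in 0 of 3. Of the other cell types, fibroblast (0 of 1) and endothelial genes (0 of 6, percentile 83.8) held none past 2-fold, and no erythroid gene passed the filter. The leukocyte list had 1 of 4 higher, CD68 at 553 against 102 on LNCaP, and the perineurial and Schwann cell list 1 of 5 lower, ERBB3 at 40.6 against 188 (percentile 82.4).

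In all, 607 of 11136 genes were past 2-fold higher on the array labelled LNCaP-AI than on LNCaP and 571 lower, and 165 and 120 were past 4-fold. When the PC3-L array took the place of the array labelled LNCaP-AI, 804 genes were higher and 501 lower than on LNCaP. These counts, too, have no replicate check.

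**Figure D2:**
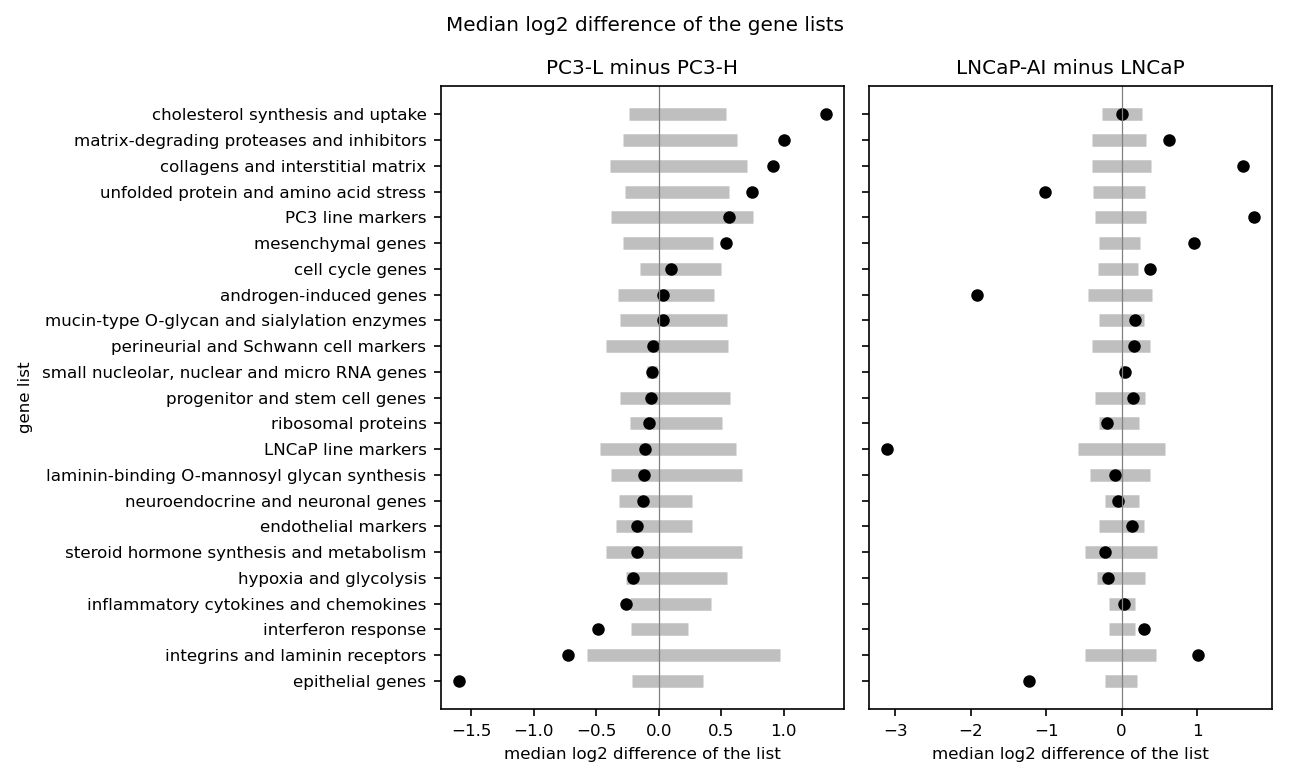
Median log2 difference of each gene list (points) in the 2 pairs, with the central 95% of medians of random lists matched on expression (grey bars); the horizontal axes of the 2 panels differ in scale, and the list of integrins and laminin receptors held no measured integrin. Epithelial genes lie below the bars in both pairs (−1.60 and −1.22), and stress genes lie above in the PC3 pair (0.74) and below in the LNCaP pair (−1.01).

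The 2 pairs share no array, and the overlap asks which genes went with the low glycan label in both. MMP1, BMP2, CCN2, TFPI2, EMP1 and AJAP1 had the largest differences among genes higher in both; their smaller log2 difference of the 2 pairs lay between 3.27 and 5.83. EPCAM, PTGFRN, CLDN7, EEF1A2, NUP210 and ASS1 had the largest among genes lower in both, with smaller differences between −3.20 and −2.79. PTGFRN, for example, was 29.4 on PC3-L and 29.4 on the array labelled LNCaP-AI, against 273 on PC3-H and 270 on LNCaP. Of 10762 genes measured in both pairs, 237 were past 2-fold higher in both, against 52.6 expected of independent lists, and 114 were lower in both, against 18.0. In opposite directions 36 and 15 genes were past 2-fold, against 45.2 and 21.0. Over all these genes the log2 differences correlated at r = 0.302 (rho = 0.129), with the same sign in 51.3%; genes are not independent replicates. The array labelled LNCaP-AI goes against its line label, and its similarity to PC3-L bears on every count of this overlap.

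**Figure D3:**
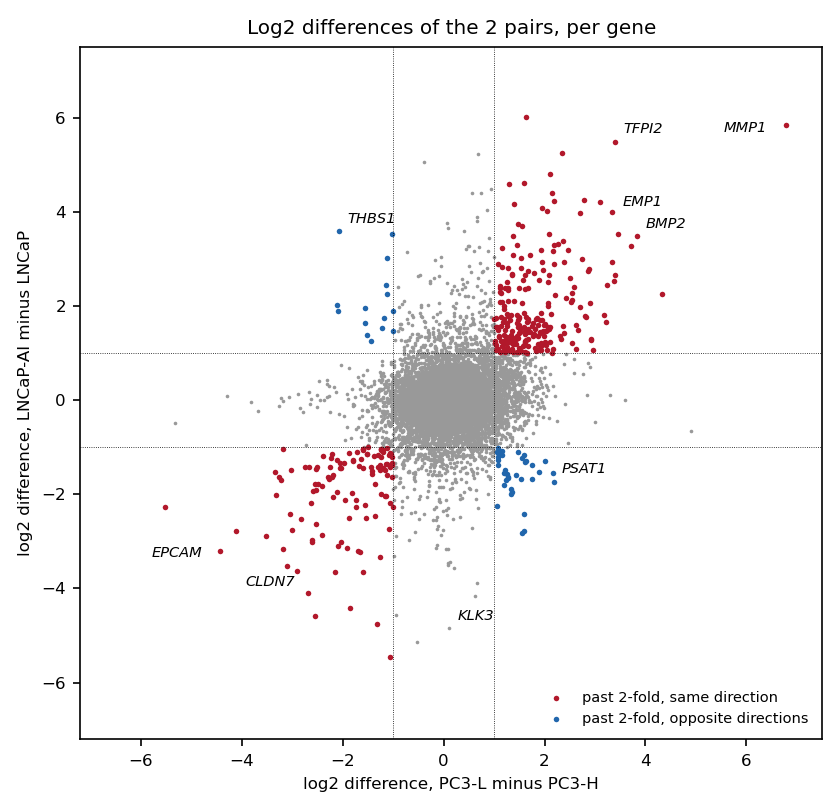
Log2 difference of each gene in the LNCaP pair (vertical) against the PC3 pair (horizontal), 1 point per gene, with dotted lines at 2-fold. Red points (237 upper right, 114 lower left) were past 2-fold in the same direction in both pairs, and blue points (36 and 15) in opposite directions.

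Low against high glycan label was then tested over both lines. The first 2 genes in each direction of the overlap, ranked by the smaller difference of the 2 pairs, had log2 differences of 6.31 ± 0.34 (SE) for MMP1, 3.66 ± 0.26 for BMP2, −3.81 ± 0.38 for EPCAM and −3.17 ± 0.24 for PTGFRN, each with an adjusted p of 0.193 by limma. Of the 12 genes named for the overlap 10 had that adjusted p; TFPI2 had a difference of 4.45 ± 0.56 (limma adjusted p = 0.219) and ASS1 −3.45 ± 0.40 (limma adjusted p = 0.208). The 12 were chosen for large differences in the same direction in both pairs, so their agreement was fixed in advance. Their limma differences come from the same 4 arrays. The pairs also cannot be counted as replication in 2 lines, since the array labelled LNCaP-AI goes against its line label. LARGE2 had a difference of −1.06 ± 0.34 (limma adjusted p = 0.486) and POMK −0.35 ± 0.59 (limma adjusted p = 1.00). At an adjusted p of 0.05, limma called 0 of 11509 genes, with 1014 at an unadjusted p under 0.05. With an intensity trend in limma's prior variance it called 115 genes, 66 higher and 49 lower with the low label (lowest adjusted p 0.0205), so the call depends on that setting. In the 5 other settings limma called 0 genes, with lowest adjusted p-values between 0.112 and 0.998.

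The line comparison in the same fit set the 2 arrays labelled LNCaP against the 2 PC3 arrays. KLK3 differed by 2.42 ± 1.21 (SE) on the log2 scale and FOLH1 by 2.67 ± 1.27, each with a limma adjusted p of 1.00; the array labelled LNCaP-AI was within 2-fold of PC3-L for both. CD44 differed by −1.69 ± 0.80 and VIM by −0.11 ± 0.36, also at an adjusted p of 1.00 by limma. No gene was called of 11509, with 225 at an unadjusted p under 0.05 by limma. Without the array labelled LNCaP-AI limma also called 0 genes, and 544 had an unadjusted p under 0.05; the only spread in that fit is the difference between PC3-H and PC3-L, so its count of 0 says nothing about a line difference.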

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

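The chromosome-window tests below were fixed before their results were seen, the mixture and compression tests after. Several results went in opposite directions in the 2 pairs; with 1 array per group none of these differences was tested. The values are the log2 difference of the LNCaP pair minus that of the PC3 pair, and the LNCaP pair rests on the array labelled LNCaP-AI, which goes against its line label. THBS1, which encodes a matricellular glycoprotein, differed by 5.66, being lower on PC3-L (−2.07) and higher on the array labelled LNCaP-AI (3.59). The syndecan SDC4 differed by 2.76 in the same way. The small Cajal body RNAs SCARNA5 and SCARNA6 differed by 3.98 and 3.58, both lower on PC3-L and higher on the array labelled LNCaP-AI. The amino acid synthesis genes PSAT1 and ASNS went the other way, with differences of −3.91 and −3.71, and the stress gene DDIT4 with −2.92. Among the lists, the median of stress genes differed by −1.75, that of the measured laminin receptor list (BCAM, CD151, CD44 and syndecans, with no integrin) by 1.74 and that of interferon response genes by 0.79.

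The array labelled LNCaP-AI lay closer to PC3-L (r = 0.961) than to LNCaP (r = 0.885), and 4 explanations were weighed: cells of the PC3 lineage on that array, LNCaP cells in a PC3-L-like state, a mixture of LNCaP RNA with RNA of PC3-L-like cells, and compression of dim probes near the floor by the authors' normalization. Against a mixture, the median LNCaP share over 23 LNCaP-specific genes was 0.0631% (bootstrap 95% interval −0.199 to 0.319), under the bound of 5%. This share takes LNCaP cells to express these genes, KLK3 and KLK4 among them, as on the LNCaP array. It does not bound a mixture with LNCaP cells in which they had fallen. Against compression, the correlation with PC3-L exceeded that with LNCaP by 0.354 in the brightest 20% of genes by mean, some of them dim on at least 1 array. Over 3081 genes at or above 87.7 on all 4 arrays it did so by 0.146 (bootstrap 95% interval 0.1225 to 0.1724). The bootstraps for the LNCaP share and for this difference resampled genes, so their intervals hold spread between genes and none between cultures. For the changed state, windows of LNCaP-AI minus PC3-L and of LNCaP minus PC3-H were compared, differences that would both span the 2 genomes. They correlated by −0.1755 relative to shuffled orders (−0.0112 with the length and density trend removed), under the bound of 0.1. A simulation gave 0.522, but it added window means of LNCaP minus PC3-H itself, which also hold what is particular to PC3-H. An earlier test of clustering gave 1.93 for the PC3 lineage and 0.727 for the changed state, past the bounds set against both, but those bounds were wrong. PC3-H minus PC3-L, labelled as 1 line, clustered at 5.70 and LNCaP minus PC3-L at only 3.37. Windows thus did not chiefly follow the line label, so neither window test can decide between the PC3 lineage and the changed state. PC3-lineage cells through a wrong label or a cross-contaminated culture stay open as an explanation. LNCaP cells in a PC3-L-like state, alone or in a mixture, stay open too. These readings assume the other 3 line labels, though PC3-L differed from PC3-H at more genes than LNCaP did (1373 against 1109). Genotypes were not analysed here.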

How the results depend on the processing

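With 1 array per group no replicate could be left out, and leaving out a line leaves the low against high fit no residual degree of freedom. The low against high fit is paired by line through its covariate; without the covariate it also called 0 genes (lowest limma adjusted p 0.112). Pair and overlap counts stayed within 1.5 times their values under quantile normalization, median centring, cyclic loess and the higher filter on dim probes. They also did so with small RNAs removed and with pseudocounts of 0 and 16. The pair counts did so with the mean over probes, for which no overlap was counted. The lower filter and no filter left all these counts unchanged, which was fixed in advance. No value lay below 17.6, so the brighter value of a gene past 2-fold exceeded the main filter, at most 34.8 on any array. At 1.5-fold, by construction, the PC3 pair had 2081 genes higher and 1187 lower, the LNCaP pair 1271 and 1372, and the overlap 867 in the same and 352 in opposite directions. At 3-fold these were 253 and 151, 268 and 201, and 120 and 7. Over all probes, a larger set, they were 1647 and 910 for the PC3 pair and 1080 and 1157 for the LNCaP pair. With the trend with gene length and density removed, genes higher on PC3-L numbered 552. Turning the PC3 pair as the descriptions have it exchanges the overlap to 51 in the same and 351 in opposite directions. Setting the array labelled LNCaP-AI against PC3-H gave 609 and 1, inflated because both differences then share PC3-H. An intensity trend in limma's prior called 115 genes for low against high; why this prior adds calls was not tested. The all-probe, trend and PC3-H settings and the pseudocounts were chosen after seeing the data. No named gene past 2-fold and no median of a list that stood apart changed sign under the normalizations, the mean over probes, the pseudocounts or the trend removal, while some values within 0.29 of 0 did. A pseudocount cannot change the sign of a gene's difference, so that part was fixed in advance. Turning the PC3 pair, not run for these values, reverses every PC3 pair sign by construction. Of 143 named gene differences, 5 moved with a pseudocount of 16 (HSPG2, CPE, CXCL8, HSD17B4 and RPS24 came within 2-fold) and at most 1 in each other setting. Of 46 list medians 2 moved, with a pseudocount of 16. Against random lists not matched on expression, PC3 markers in the PC3 pair (percentile 98.2) and ribosomal proteins in the LNCaP pair (2.45) stood apart, and with the trend removed small RNA genes did in the PC3 pair (100). Signal over the floor, with array medians near 40.8, limits what dim genes can show.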

Other observations

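The comparison of the array labelled LNCaP-AI with PC3-L, and its genes, were chosen after the values were seen. The 6 genes most above PC3-L on the array labelled LNCaP-AI were PCDHB5 (18.7-fold, 458 against 23.5), SIRPB1 (5.86-fold), PCDHB10 (5.52-fold), PCDHB2 (5.50-fold), PCDHB16 (5.48-fold) and the VIP receptor gene VIPR1 (4.93-fold). The PCDHB genes are clustered protocadherins with similar sequences, so the individual members are uncertain, and no enrichment of them was tested. PCDHB5 was 130 on LNCaP and 25.5 on PC3-H. Lower on that array were the chemokine CXCL8 (10.4-fold), the desmosomal cadherin DSC3 (8.66-fold), the cytokine LIF (5.82-fold), ANGPT2 (62.1 against 327), ASNS (5.15-fold) and MSMO1 (5.08-fold).

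Cholesterol genes were lower than on PC3-L in 7 of 16 and higher in 1 (median −0.90, percentile 0 of the random lists), and stress genes were lower in 5 of 15 and higher in 0 (median −0.77, percentile 0). Inflammatory genes were lower in 3 of 16 (median −0.27, percentile 0.32). Interferon response genes were higher in 1 of 22 (median 0.22, percentile 99.8), and the laminin receptor list, with no integrin measured, was past 2-fold in 0 of 5 (median 0.51, percentile 99.7). Androgen-induced genes (0 of 8 past 2-fold, median −0.05, percentile 32.3) and epithelial genes (2 of 18 lower, median −0.05, percentile 13.6) did not stand apart.

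More genes were past 2-fold higher than lower on PC3-L against PC3-H, at a ratio of 2.29, and the test of the gene length and density trend was chosen after this was seen. Log2 values relative to the other 3 arrays correlated across 11141 genes with gene length at r = 0.212 on PC3-L and −0.180 on PC3-H, and with the span of neighbouring genes at 0.266 and −0.201, against values between −0.0591 and −0.00134 on the LNCaP arrays. With this trend removed the ratio was 1.03. The removal also set the mean difference to the pair's former median, and what this shift contributed to the ratio was not separated. A technical bias of the labelled RNA may account for the asymmetry, though a biological trend with length or density would look alike. A difference in scale or distribution left by the authors' normalization cannot be told apart from these: quantile normalization left a ratio of 1.71, between the bounds set for and against it, median centring left 2.86 and cyclic loess 2.05, and the ratio has no replicate spread. The separation of the cultures by glycan stays open as an untested biological explanation.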
